A study of Mus musculus with 4 samples.

How the data were processed

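Single-cell suspensions were prepared from collecting lymphatic vessels and the tissue around them, dissected from 4 male and 4 female C57BL/6J mice aged 12 to 14 weeks. Vessels from 4 anatomical regions were combined for each mouse, per the labels' protocols. Cells were tagged with multiplexing oligonucleotides, pooled within each sex and captured as droplets, with a gene expression library and an oligonucleotide library per sex. The deposited matrix holds raw UMI counts, that is, counts of distinct captured molecules per gene and cell barcode, made by the authors with Cell Ranger 7.1.0 per the file headers. The submitters' processing notes name Cell Ranger 7.1.0, Seurat 4.3.0.1 and the mouse build mm10, and the role of Seurat is not given in the sources used here. The annotation used for counting is not given in the sources used here either, so gene positions were taken from GENCODE release M21 on GRCm38 (mm10).

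The matrix holds 24046 barcodes, 32285 genes and 12 oligonucleotide tags. Barcodes carry a number suffix from 1 to 8, and no label says which mouse or sex a suffix stands for. Each suffix had a single main tag, which held 84.41% to 88.96% of its tag UMIs, and the same 4 tags served suffixes 1 to 4 and suffixes 5 to 8. No barcode sequence was shared within either set of 4 suffixes (12 pairs), whereas 44 were shared across the sets (16 pairs), so the sets were treated as 2 capture wells when doublets were scored. Sex was not assigned to any cell. The matrix was therefore analysed as 1 pooled sample, as laid down before the data were examined for the case in which barcodes name neither mouse nor sex. The planned comparisons of female with male mice, of expression and of class shares, were not run.

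Barcodes with at least 500 UMIs, at least 300 genes and under 15% mitochondrial UMIs were kept, which removed 380 and left 23666. Doublets were scored within each well against simulated doublets (2 per cell, expected rate 6%), with the threshold set at the minimum between the modes of the simulated scores. This removed 518 cells (2.19%) and left 23148. When 300 doublets made by adding deposited cells were mixed in, 42.3% of them were called, so undetected doublets remained among the cells. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes (20 bins of mean) gave 30 principal components, a graph of 15 nearest neighbours weighted by shared neighbours, and Leiden clusters at resolution 1.0. The 123 genes of the 12 fixed lists were left out of the variable genes, so that the clusters were not built from them, and none of them was among the 130 markers of the 23 candidate cell classes.

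Markers and lists were fixed before the data were examined, but the rule that turns marker levels into a class name was not. The rule used first took the class with the highest mean log2 fold of its markers over all other cells, with a pseudocount of 10 CPM. It named cluster 15, in which 91.4% of cells had a UMI of the lymphatic marker Prox1, blood endothelial-like (score 3.11, against 2.34 for lymphatic endothelial). After the marker profiles and leading genes of the clusters had been seen under pseudocounts of 1, 10 and 50 CPM, the rule was replaced, and Trpv4 values per cluster had been seen by the time the replacement was put in place. The rule reported here standardises log2(CPM + 10) of each marker across clusters and averages it over a class's markers, and it gave cluster 15 a score of 2.26 for lymphatic and 2.10 for blood endothelial. A cluster took the highest-scoring class with at least 3 markers found in 10% of its cells. It stayed unnamed if fewer than 3 of these were 2-fold up, if another class had more markers among its 10 leading genes (by fold, pseudocount 1 CPM), or if it was shallow with no own marker among them. Of 41 clusters, 35 were named and 2168 cells (9.4%) stayed unnamed. The rules named 7 clusters with 1859 cells differently, and values under the rule used first are given with the other alternatives.

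Counts were summed over the cells of a class and scaled to CPM by the total UMIs of that class with exact Poisson 95% intervals. Ratios of CPM carry exact conditional binomial intervals, and shares of cells carry exact Clopper-Pearson intervals. For shares at equal depth, each cell was thinned at random to 1000 UMIs and shallower cells were left out. All intervals cover counting error only. Cells are not replicates, and no test was made. Since the labels do not say what a suffix stands for, suffixes were not used as replicates: the number of suffixes that share the order of Trpv4 levels is given without a test, and differences in list genes were not compared across suffixes. The lowest, median and highest of the 8 suffixes are given as values of unlabelled samples, for Trpv4 in macrophage-like, smooth muscle-like, lymphatic endothelial-like and blood endothelial-like cells. Trpv4 was named in every class. From each list the members at 10 CPM or more in lymphatic endothelial-like, smooth muscle-like or macrophage-like cells were named, at most the 4 highest per list and class, with any member in a count of 5 or fewer. Levels of 2 genes that the rule names are not used here. A few genes outside this rule are named after their values were seen: those that set cluster 36 apart, and those named for classes other than these 3.

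The computation of the intervals was checked on simulated Poisson counts for 12271 genes, drawn for sums of 650 and 1350 cells, with 200 genes changed. These counts follow the model that the intervals assume and hold no variation between cells or mice. The check therefore cannot show how well the intervals cover such variation in the real cells. The 95% interval of the ratio held the true value for 98.0% of 100 genes raised 2-fold, 99.0% of 100 genes raised 4-fold and 95.4% of unchanged genes. Intervals of unchanged genes lay apart for 0.530%. Alternatives varied the cell filter, the Leiden resolution, doublet removal, the variable genes, the way CPM was averaged, the thinning depth and the denominator, and left out each suffix in turn. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2, scikit-image 0.26.0 and matplotlib 3.10.9 were used.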

Results

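Gene expression was measured in single cells from collecting lymphatic vessels, the muscular vessels that pump lymph, and from the tissue around them. The study's title names TRPV4, a calcium-permeable cation channel opened by stretch, swelling and warmth, as a regulator of the contractions of these vessels. The 24046 deposited barcodes held 232753017 gene UMIs, with a median of 8684.5 UMIs and 2866 genes per barcode. The 8 barcode suffixes held 2375 to 3315 barcodes and 23828933 to 32467001 gene UMIs each. After filtering, 23148 cells were left, of which 2168 stayed unnamed and the others fell into 17 named classes. The largest were 8621 fibroblast-like and 5111 macrophage-like cells, followed by 1351 smooth muscle-like, 1026 mesothelial-like, 942 dendritic-like, 649 lymphatic endothelial-like, 535 pericyte-like and 460 blood endothelial-like cells.

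The first question was which cells of the vessel wall and its surroundings carry Trpv4 transcripts. Trpv4 (ENSMUSG00000014158) is a protein-coding gene on the minus strand of chromosome 5, from 114622152 to 114658421 on GRCm38. Its level was highest in macrophage-like cells, at 51.3 CPM (95% interval 49.1 to 53.7, 1990 UMIs). Lymphatic endothelial-like cells held 17.7 CPM (15.2 to 20.6, 168 UMIs), and smooth muscle-like cells, in which muscle of lymphatic and of blood vessels was not told apart, 1.25 CPM (0.685 to 2.10, 14 UMIs). The macrophage-like level was 2.89 times (2.47 to 3.41) the lymphatic endothelial-like level, which in turn was 14.2 times (8.20 to 26.4) the smooth muscle-like level. Both orders held in 8 of 8 barcode suffixes. Over the suffixes the macrophage-like level ran from 37.2 to 64.0 CPM (median 47.2). The lymphatic endothelial-like level ran from 10.5 to 26.6 CPM (median 19.1), and the smooth muscle-like level from 0 to 1.96 CPM (median 1.64). The macrophage-like and lymphatic endothelial-like ranges are wider than the Poisson intervals of the pooled counts. A single suffix holds only part of those UMIs and so has a larger counting error. The ranges therefore do not show by themselves whether suffixes differ beyond counting error.

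Other classes with Trpv4 were blood endothelial-like cells at 27.9 CPM (22.8 to 33.8), mesothelial-like cells at 21.8 CPM (19.6 to 24.3) and epithelial-like cells at 9.61 CPM (7.50 to 12.1). The epithelial-like cells all came from suffixes 1 to 4, and their clusters 29 and 28 differed, at 32.9 and 1.81 CPM. Fibroblast-like cells held 3.21 CPM (2.86 to 3.59), which was 5.53-fold (4.56 to 6.69) below the lymphatic endothelial-like level and 3.49 times (0.958 to 28.9) the level of B-like cells, the background class, an interval that includes 1. Monocyte-like cells (cluster 23, which scored 2.85 for monocyte and 5.52 for neutrophil and was unnamed under the rule used first) held 8.59 CPM (5.09 to 13.6) and proliferating-like cells 11.3 CPM (7.30 to 16.6), of which cluster 35 held 17.8 CPM (23 UMIs) and cluster 38 held 2.16 CPM (2 UMIs). Dendritic-like cells, which share a myeloid origin with macrophages, held 1.66 CPM (0.927 to 2.73), and the macrophage-like level was 31.0 times (18.8 to 55.5) theirs. Levels in pericyte-like (1.01 CPM, 0.276 to 2.59), T-like (1.07 CPM, 0.129 to 3.86), innate lymphoid-like (0.871 CPM, 0.105 to 3.14), NK-like (3.48 CPM, 0.718 to 10.2) and mast-like cells (7.37 CPM, 1.52 to 21.5) rested on 2 to 4 UMIs each. No Trpv4 UMI was found in 104 Schwann-like cells, with a 95% interval up to 9.50 CPM. B-like cells, taken as the background class, held 0.920 CPM (0.111 to 3.32). The smooth muscle-like level was 1.36 times theirs (0.313 to 12.4), so Trpv4 above background was not detected in smooth muscle-like cells. The B-like level rests on 2 UMIs, and the wide interval of the ratio leaves room for a several-fold excess. Over the suffixes the blood endothelial-like level ran from 7.40 to 44.4 CPM (median 28.8). Blood endothelial-like cells exceeded lymphatic endothelial-like cells by 1.57 times (1.22 to 2.02), in 6 of 8 suffixes. That order depended on how classes were named: under the rule used first the log2 ratio was 0.26, with an interval from -0.47 to 1.08. The blood endothelial-like class then held 1042 cells, 582 of them from cluster 15, and the lymphatic endothelial-like class only 67. This ratio therefore compares other sets of cells and is not a second measure of the same order.

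**Figure D1:**
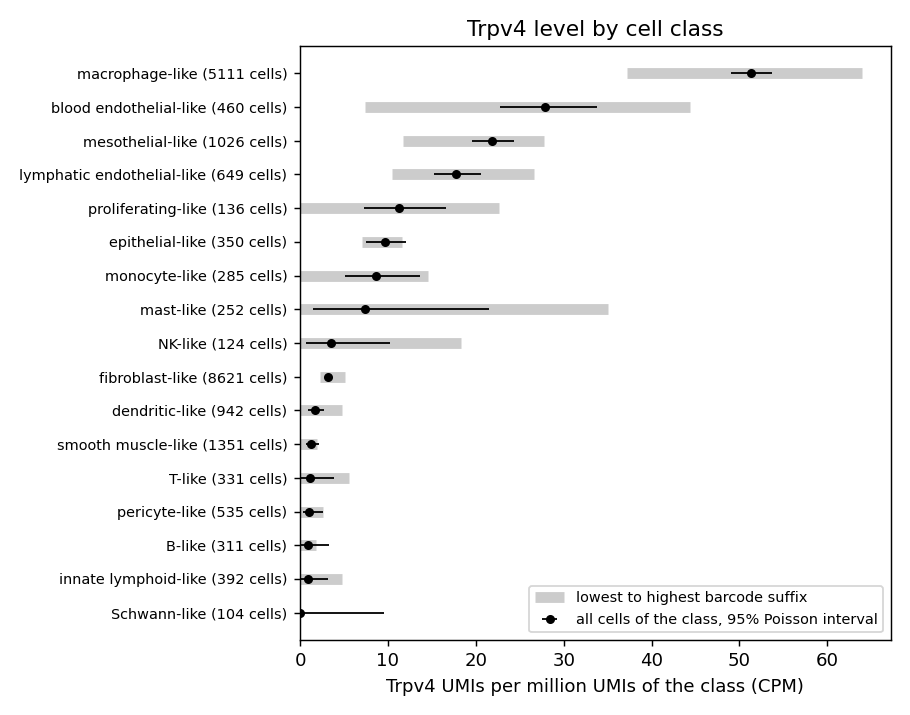
Trpv4 level (CPM) in each cell class, on a linear axis. Points are all cells of a class with exact Poisson 95% intervals, and grey bars run from the lowest to the highest of the barcode suffixes. Macrophage-like cells stand at 51.3 CPM, lymphatic endothelial-like cells at 17.7 CPM and smooth muscle-like cells at 1.25 CPM.

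Shares of cells with a Trpv4 UMI followed the same order in these 3 classes. A UMI was found in 30.8% of macrophage-like cells (29.5% to 32.1%, median 7308 UMIs), 19.3% of lymphatic endothelial-like cells (16.3% to 22.5%, median 8167) and 1.04% of smooth muscle-like cells (0.568% to 1.73%, median 8278). In B-like cells the share was 0.643% (0.0780% to 2.30%, median 4822), and the smooth muscle-like share lay within that interval. Shares were 26.0% in mesothelial-like (23.4% to 28.8%, median 13709), 15% in blood endothelial-like (11.9% to 18.6%, median 5951, but 8.62% of 232 cells under the stricter cell filter) and 3.45% in fibroblast-like cells (3.07% to 3.85%, median 11110). After thinning to 1000 UMIs the shares were 4.75% (4.19% to 5.37%) in macrophage-like, 1.46% (0.668% to 2.75%) in lymphatic endothelial-like and 0.228% (0.0471% to 0.666%) in smooth muscle-like cells, beside 0.324% (0.00819% to 1.79%) in B-like cells. Thinning left out 0, 31, 38 and 2 cells of these classes, and at this depth the lymphatic endothelial-like and B-like intervals overlapped.

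The lymphatic endothelial-like class was made of cluster 15, with 582 cells, and cluster 36, with 67. Both held Prox1, the transcription factor of lymphatic identity, in 91.4% and 98.5% of cells. Lyve1 and Ccl21a, markers of initial lymphatic vessels, were found in 98.5% of cells of cluster 36 but in 8.08% and 3.95% of cells of cluster 15. Trpv4 stood at 17.8 CPM (15.1 to 20.8) in cluster 15 and 17.5 CPM (9.98 to 28.4) in cluster 36. No difference in Trpv4 between the clusters was seen, but cluster 36 held only 16 Trpv4 UMIs and its wide interval leaves room for one. Other fixed-list genes did differ. Piezo2, a mechanically gated channel, was 215 times (146 to 329) higher in cluster 36, at 679 against 3.16 CPM, and Kcnn3, a calcium-activated potassium channel, 27.5 times (18.7 to 41.3) higher. Ptgs1, which encodes cyclooxygenase 1, was 16.7 times (9.56 to 32.4) higher in cluster 15, at 219 against 13.1 CPM, and Nos3, the endothelial nitric oxide synthase, 4.06 times (3.09 to 5.44) higher. Of 68 list genes at 20 CPM or more in either cluster, the Poisson intervals lay apart for 43, of which 20 were higher in cluster 15 and 23 in cluster 36. Cluster 15 also held blood endothelial markers, with Plvap in 90.5%, Fabp4 in 85.1% and Flt1 in 18.9% of its cells, against 31.3%, 31.3% and 2.99% in cluster 36. In blood endothelial-like clusters 24 and 27, Plvap was found in 29.3% and 80.4% of cells and Flt1 in 98.9% and 81.4%. Prox1 was found there in only 3.38% and 18.6% of cells. The lymphatic markers Flt4 and Mmrn1 were found in 76.8% and 82.5% of cells of cluster 15, against 13.5% and 1.88% in cluster 24 and 6.19% and 1.55% in cluster 27. By score the name of cluster 15 was a close call, at 2.26 for lymphatic and 2.10 for blood endothelial. The rule used first named it blood endothelial-like, and it stayed unnamed with all deposited barcodes or at resolution 2.0, so levels given for the lymphatic endothelial-like class rest on counting this cluster as lymphatic.

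The second question was how signalling genes are divided among lymphatic endothelial-like, smooth muscle-like and macrophage-like cells. Among 15 TRP and mechanosensitive channels, 7, 8 and 6 reached 10 CPM in these classes. Piezo1, a channel gated by membrane tension, was highest in lymphatic endothelial-like cells at 217 CPM (208 to 227), against 68.7 CPM in macrophage-like and 28.7 CPM in smooth muscle-like cells. Trpv2 showed the opposite order, with 88.7 CPM (83.2 to 94.4) in smooth muscle-like and 1.80 CPM in lymphatic endothelial-like cells, and was higher still in pericyte-like cells at 182 CPM. The names of pericyte-like clusters 17 and 31 were close calls (2.57 against 2.31 and 2.46 against 2.36 for smooth muscle), both were smooth muscle-like under the rule used first, and the smooth muscle gene Acta2 was found in 100% and 91.8% of their cells. Trpm7 was highest in macrophage-like cells at 246 CPM (241 to 251). Pkd1 and Pkd2 stood at 72.6 and 77.2 CPM in smooth muscle-like cells and at 38.0 and 38.8 CPM in lymphatic endothelial-like cells. Piezo2 reached 68.5 CPM in lymphatic endothelial-like cells, nearly all of it from cluster 36.

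Among nitric oxide and cGMP genes, 7, 8 and 2 reached 10 CPM in lymphatic endothelial-like, smooth muscle-like and macrophage-like cells. Nos3 stood at 218 CPM (208 to 227) in lymphatic endothelial-like cells, 93.2 CPM in blood endothelial-like cells and 1.07 CPM in smooth muscle-like cells. Of the 11 members, 8 were highest of the 3 classes in smooth muscle-like cells and 1, Nos3, in lymphatic endothelial-like cells. The guanylate cyclase subunit Gucy1a1 stood at 396 CPM (385 to 408) in smooth muscle-like and 65.7 CPM in lymphatic endothelial-like cells. Prkg1, the cGMP-dependent kinase, reached 1370 CPM (1349 to 1392) and 800 CPM, the phosphodiesterase Pde3a 702 and 25.0 CPM, and Cav1 707 and 474 CPM. Ddah2 stood at 93.9 CPM in smooth muscle-like, 66.3 CPM in lymphatic endothelial-like and 12.5 CPM in macrophage-like cells.

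Prostanoid synthesis genes were spread over all 3 classes. Ptgs1 was highest in lymphatic endothelial-like cells at 199 CPM (190 to 208), against 32.0 CPM in macrophage-like and 1.25 CPM in smooth muscle-like cells. Macrophage-like cells held Hpgds, a prostaglandin D synthase, at 380 CPM (374 to 387), Tbxas1, the thromboxane synthase, at 319 CPM (314 to 325) and Pla2g4a at 34.0 CPM. Ptgis, the prostacyclin synthase, stood at 51.8 CPM (47.6 to 56.2) in smooth muscle-like cells and was highest in mesothelial-like cells at 763 CPM. Ptgs2 stood at 37.2 CPM in smooth muscle-like cells (6.70 CPM in the larger cluster 7 and 147 CPM in cluster 22) and 20.8 CPM in each of the other 2 classes, and was highest in fibroblast-like cells at 390 CPM. Ptges3 ranged from 168 to 210 CPM over the 3 classes, and Ptges2 stood near 11 CPM in lymphatic endothelial-like and smooth muscle-like cells. Of 9 prostanoid receptors, the thromboxane receptor Tbxa2r stood at 42.4 CPM (38.7 to 46.4) in smooth muscle-like and 35.6 CPM (31.9 to 39.6) in lymphatic endothelial-like cells, whose intervals overlapped. Ptger4 stood at 76.8 CPM (74.1 to 79.6) in macrophage-like cells and was highest in dendritic-like cells at 114 CPM, and Ptgir and Ptger3 reached 19.7 and 10.6 CPM in smooth muscle-like cells.

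Genes of pacemaking and excitability were concentrated in smooth muscle-like cells, where 11 of 15 reached 10 CPM and 10 were highest of the 3 classes. Cacna1c, the L-type calcium channel, stood at 1063 CPM (1044 to 1083), and Ano1, a calcium-activated chloride channel, at 311 CPM (301 to 322), against 3.70 and 1.16 CPM in lymphatic endothelial-like cells. The calcium pump Atp2a2 reached 504 CPM in smooth muscle-like and 223 CPM in lymphatic endothelial-like cells. The exceptions were Itpr1, at 411 CPM (399 to 425) in lymphatic endothelial-like and 307 CPM (297 to 318) in smooth muscle-like cells, and the connexin Gja1, at 246 CPM (236 to 256) and 7.34 CPM. Gjc1 stood at 121 CPM in smooth muscle-like and 48.5 CPM in lymphatic endothelial-like cells, and Slc12a2 at 75.0 CPM in smooth muscle-like and 14.1 CPM in macrophage-like cells. Of 6 endothelial potassium channels and connexins, Gja4 (42.5 CPM, 38.4 to 46.8), Panx1 (19.3 CPM, 16.6 to 22.3) and Kcnn3 (15 CPM, 12.6 to 17.7) were highest of the 3 classes in lymphatic endothelial-like cells, with Kcnn3 at 4.21 CPM in cluster 15 and 116 CPM in cluster 36. Over all classes Gja4 was highest in pericyte-like cells, at 178 CPM, with 48.2 CPM in blood endothelial-like cells. Since the rule used first named the pericyte-like clusters smooth muscle-like, the order of Gja4 depends on the naming. Panx1 was highest in NK-like cells, at 62.6 CPM. Panx1 stood at 13.4 CPM in smooth muscle-like cells, from 7.63 CPM in cluster 7 and 34.8 CPM in cluster 22.

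Receptors for vasoactive substances also differed. Chrm3, a muscarinic acetylcholine receptor, stood at 699 CPM (682 to 716) in lymphatic endothelial-like cells, the highest of all classes, and at 8.06 CPM in smooth muscle-like cells. Ednra, an endothelin receptor, stood at 109 CPM (103 to 115) in smooth muscle-like cells and 0.211 CPM in lymphatic endothelial-like cells. Ednrb was highest in macrophage-like cells at 578 CPM (571 to 586), followed by lymphatic endothelial-like cells at 284 CPM and smooth muscle-like cells at 37.7 CPM. Macrophage-like cells also held the histamine receptor Hrh1 at 87.8 CPM (84.9 to 90.8), against 0.739 CPM in lymphatic endothelial-like cells. Npr1 stood at 23.0 CPM in macrophage-like and 79.5 CPM in lymphatic endothelial-like cells. Esr1, an oestrogen receptor, stood at 63.2 CPM (60.7 to 65.8) in macrophage-like, 51.0 CPM (46.6 to 55.8) in lymphatic endothelial-like and 12.5 CPM (10.5 to 14.8) in smooth muscle-like cells, from 7.05 CPM in cluster 7 and 32.3 CPM in cluster 22.

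All 7 lymphatic valve genes were highest of the 3 classes in lymphatic endothelial-like cells. Nfatc1 stood there at 362 CPM (350 to 375), Itga9 at 292 CPM (281 to 303), Efnb2 at 195 CPM (186 to 204) and Foxc2 at 112 CPM (105 to 119). Itga9 and Nfatc1 also stood at 132 and 52.3 CPM in smooth muscle-like and 96.7 and 58.3 CPM in macrophage-like cells. Of 10 cytokine and chemokine genes, 6 were highest of the 3 classes in macrophage-like cells, among them Cxcl2 at 4488 CPM (4467 to 4509), Ccl2 at 1818 CPM (1805 to 1832) and Tgfb1 at 462 CPM (455 to 469). Of the 3 classes, smooth muscle-like cells led in Cxcl1, at 1325 CPM (1304 to 1347), and Il6, at 286 CPM (276 to 296). Lymphatic endothelial-like cells led the 3 in Il33, at 79.2 CPM (73.6 to 85.1), and Csf1, at 64.3 CPM (59.3 to 69.6). Over all classes Cxcl1 and Csf1 were highest in fibroblast-like cells, at 2782 and 309 CPM, and Il6 in pericyte-like cells, at 371 CPM.

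All 13 genes of the dissociation response list reached 10 CPM in each of the 3 classes. How much of this arose during dissociation was not tested. Junb stood at 5366 CPM in smooth muscle-like, 3666 CPM in macrophage-like and 3066 CPM in lymphatic endothelial-like cells, and Fos at 4872, 2687 and 1963 CPM. Jun reached 3621 CPM in lymphatic endothelial-like cells, with Atf3 at 2908 CPM and Ier3 at 1966 CPM. Egr1 stood at 3556 CPM in smooth muscle-like cells, and Egr1 and Dusp1 at 3314 and 3053 CPM in macrophage-like cells. Of the sex chromosome list, in macrophage-like, smooth muscle-like and lymphatic endothelial-like cells, Ddx3x stood at 511, 313 and 321 CPM, Xist at 296, 283 and 174 CPM and Ddx3y at 116, 130 and 104 CPM. Levels of Xist and Ddx3y pool suffixes that ranged from 0.0318 to 646 CPM and from 0.479 to 157 CPM, so they are not read as differences between classes. Kdm6a stood at 159 CPM in macrophage-like and 83.7 CPM in lymphatic endothelial-like cells, and Kdm5c at 71.3 CPM in smooth muscle-like cells.

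**Figure D2:**
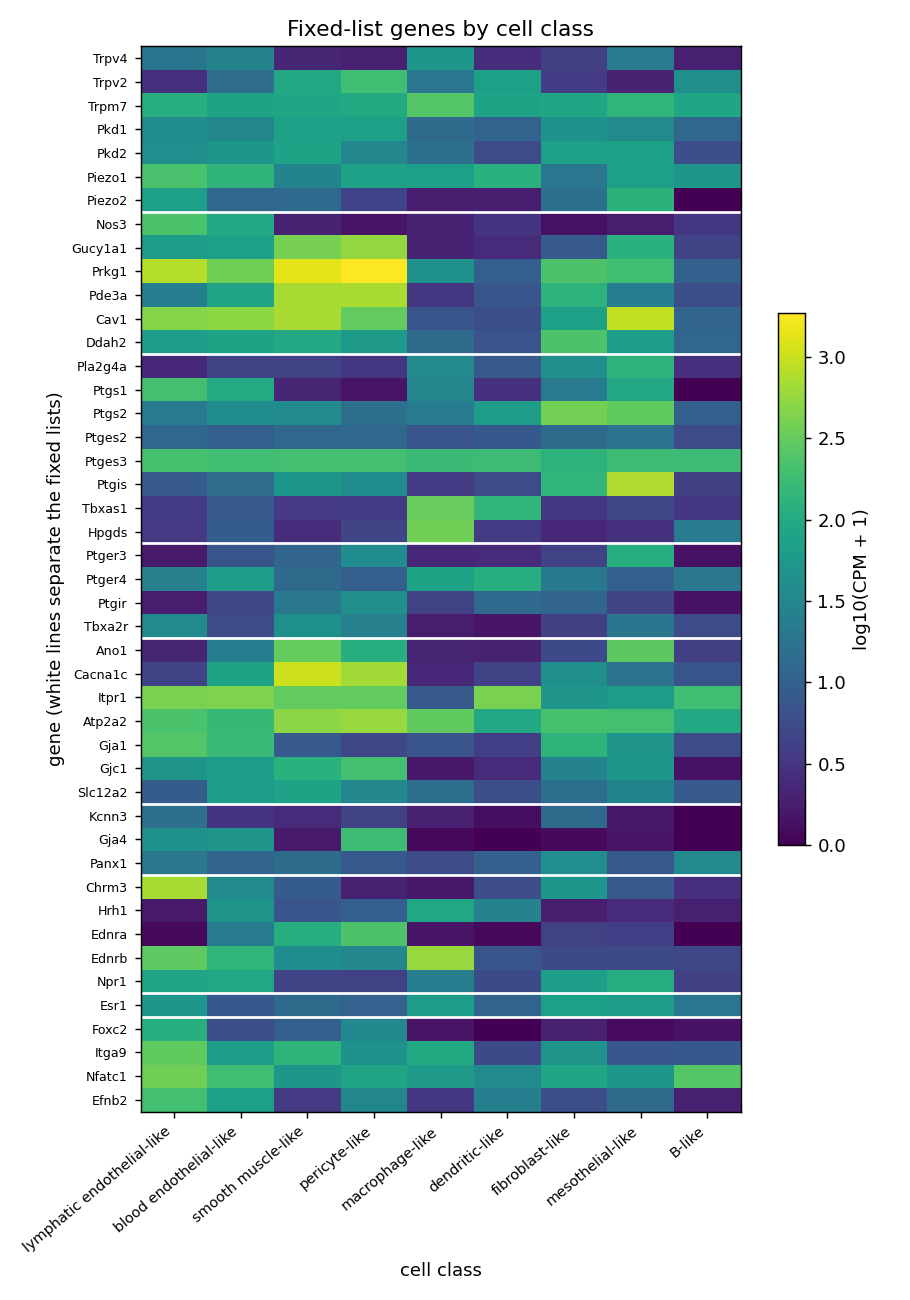
Levels of 45 fixed-list genes in 9 cell classes, as log10(CPM + 1), with 1 gene per row and white lines between the 9 lists drawn. Nos3, Ptgs1 and Chrm3 are highest in lymphatic endothelial-like cells, at 218, 199 and 699 CPM, and Cacna1c and Ano1 in smooth muscle-like cells, at 1063 and 311 CPM.

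The study also collected both sexes, with 4 mice each. Because no label ties a barcode suffix to a mouse or a sex, female and male cells were not compared here.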

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

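The matrix also holds oligonucleotide tags that no comparison used. Of the 12 tags, 8 were the main tag of no barcode suffix, and each gave more UMIs than the 3 that a count of 0 allows. That limit is a low bar here, as these 8 tags gave 1201 of 102985749 tag UMIs (0.00117%) in all, and no explanation was tested. CMO309 gave 486 UMIs, CMO306 gave 376, CMO308 gave 184, CMO311 gave 89, CMO312 gave 40, CMO310 gave 11, CMO305 gave 10 and CMO307 gave 5. Most UMIs of CMO306 came from suffixes 4 and 8 (138 and 173), of CMO308 from suffixes 2 and 6 (69 and 85), and of CMO309 from suffixes 3 and 7 (179 and 227).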

How the results depend on the processing

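Naming by the rule used first, and giving every cluster its best-scoring class, were alternatives chosen after the data were seen. Over 70 results and 1013 alternative values, 980 stayed within the interval of the reported value (or within 1.5 times of a count), 33 moved and 0 changed direction. Only ratios between classes have a direction, and 36 of the 70 results were counts of list members. Leaving out each suffix in turn moved 0 of 400 values, with Trpv4 at 16.6 to 18.9 CPM in lymphatic endothelial-like, 1.14 to 1.41 in smooth muscle-like and 49.4 to 52.7 in macrophage-like cells. Each of these values keeps most of the same counts, so this check could show little movement. The pericyte-like level, from 4 UMIs, went from 1.01 to 0.626 CPM without suffix 6. Classes also changed in their cells. The pericyte-like class (535 cells) had no cells under the rule used first, which named both its clusters smooth muscle-like, so it has no value there, and fell to 60 with all deposited barcodes. The lymphatic endothelial-like class fell from 649 to 67 cells under the rule used first, 73 with all deposited barcodes and 68 at resolution 2.0, as its larger cluster was then named blood endothelial-like (rule used first) or left unnamed. The thinned share of the latter was then 0% in each case. Under the rule used first Trpv4 was 17.5 CPM in lymphatic endothelial-like and 20.8 CPM in blood endothelial-like cells, a log2 ratio of 0.26, and the members at 10 CPM were 2 for prostanoid synthesis, 1 for prostanoid receptors and 1 for sex steroid receptors in lymphatic endothelial-like, and 2 for potassium channels and connexins in smooth muscle-like cells. With all deposited barcodes Trpv4 was 53.8 CPM in macrophage-like and 0 CPM (0% of cells) in pericyte-like cells, the log2 ratio of macrophage-like to lymphatic endothelial-like cells was 1.80, and members at 10 CPM were 1 for prostanoid receptors in lymphatic endothelial-like, and 2 for potassium channels and connexins and 4 for valve genes in smooth muscle-like cells. At resolution 2.0 prostanoid and sex steroid receptors each had 1 member in lymphatic endothelial-like cells, and at 0.5 the macrophage-like share was 28.6%. With every cluster named, macrophage-like cells held 44.1 CPM (25.6% of cells), with 4 pacemaking genes, 1 potassium channel or connexin and 2 sex steroid receptors at 10 CPM. The blood endothelial-like share was 8.62% under the stricter cell filter, the pericyte-like share 1.74% without doublet removal, and the macrophage-like level 53.9 CPM with the lists among the variable genes. As a mean over cells, Trpv4 was 21.4 CPM in blood endothelial-like, 15.2 in epithelial-like and 3.88 in fibroblast-like cells. Thinning to 2000 UMIs gave 3.55% of lymphatic endothelial-like, 9.66% of macrophage-like and 0.594% of fibroblast-like cells. The cause of these moves was not tested, apart from the change of cells in these classes and the depth set by thinning. Small counts limit the smooth muscle-like, pericyte-like and lymphoid levels, which rest on 14 UMIs or fewer. Female and male samples were not compared, paired or otherwise, because no label or barcode name ties a suffix to a mouse or sex. A test of classes paired within suffixes would need no sex label, but was left out because no label says that each suffix is a separate mouse. Differences between classes therefore rest on counting intervals and, for Trpv4, on the number of suffixes with the same order. The alternatives of the comparisons of the sexes and those with DESeq2 or edgeR were not run, as no test was made.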

Other observations

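The sub-clusters, the test on fibroblast-like clusters and the use of all 7 macrophage markers beside 5 were chosen only after the values had been seen. Within the lymphatic endothelial-like class, clustering without the fixed lists gave 7 sub-clusters at resolution 0.5. All 7 lymphatic valve genes had their highest CPM in the same sub-cluster, of 73 cells, where Foxc2 stood at 204 CPM (181 to 230), Itga9 at 428 CPM (394 to 464) and Cldn11 at 95.7 CPM (80.1 to 113). Resolution 0.8, at which the class was first looked at, gave 9 sub-clusters, and again all 7 genes were highest in a single one, of 56 cells, with Foxc2 at 256 CPM (223 to 293). For 6 of the 7 genes at each resolution the interval overlapped that of at least 1 other sub-cluster, in part because 1 of these held 30 shallow cells (median 803 UMIs): at 0.8 Efnb2 stood at 249 CPM (216 to 285) against 242 CPM (220 to 265) in the next. Trpv4 was not highest there: it stood at 17.4 CPM (11.1 to 25.9) in the 73 cells and 12.1 CPM (5.79 to 22.2) in the 56 cells.

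Trpv4 also differed between clusters of 1 class. In epithelial-like cells it stood at 32.9 CPM (25.2 to 42.3) in cluster 29 and at 1.81 CPM (0.866 to 3.32) in cluster 28. Fibroblast-like clusters ran from 1.21 CPM (0.582 to 2.23) in cluster 13 to 5.45 CPM (4.23 to 6.91) in cluster 9. Cluster 3 held 5.19 CPM (4.18 to 6.37), and the lower limits of clusters 9 and 3 lay above the B-like upper limit of 3.32 CPM. Blood endothelial-like clusters 27 and 24 were less clearly apart, at 35.8 CPM (27.5 to 45.8) and 20.8 CPM (14.9 to 28.2), as their intervals overlapped. Among macrophage-like cells, cluster 0 held 58.9 CPM (55.5 to 62.5), cluster 1 held 43.7 CPM (40.3 to 47.3) and cluster 11 held 45.4 CPM (40.3 to 51.0). These levels pool suffixes in unequal parts, as suffixes 5 to 8 gave 78.0% of cluster 0 and 51.0% of cluster 1. Unnamed cluster 5, with 1009 shallow cells (median 1979 UMIs), held 52.3 CPM (43.8 to 62.1).

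Because macrophage-like cells hold most Trpv4 UMIs per cell, Trpv4 elsewhere may come from their free RNA or from droplets that also held a macrophage. If free RNA were the source, Trpv4 would stay at or under a carry-over level set by the best-carried of 5 macrophage genes: 0.670 CPM in lymphatic endothelial-like, 2.54 in blood endothelial-like, 3.65 in mesothelial-like, 0.549 in epithelial-like and 0.562 in fibroblast-like cells. Observed levels had lower limits of 15.2, 22.8, 19.6, 7.50 and 2.86 CPM, also above the level from all 7 macrophage markers, which argues against this source. In cells with no UMI of the 5 genes, Trpv4 stood at 16.7 CPM in lymphatic endothelial-like, 29.0 in blood endothelial-like, 19.4 in mesothelial-like and 11.5 in epithelial-like cells, with lower limits above the B-like upper limit of 3.32 CPM, which argues against mixed droplets. What stays open is smooth muscle-like cells, whose lower limit of 0.685 CPM exceeds the carry-over level from 5 genes (0.536 CPM) but not that from all 7 (0.861 CPM), and also mixed droplets in smooth muscle-like (1.19 CPM) and fibroblast-like cells (3.20 CPM).

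The 8 barcode suffixes are samples that the labels put in no group. From suffix 1 to suffix 8, Xist stood at 639, 646, 634, 615, 0.0327, 0.0364, 0.0318 and 0.0340 CPM, and Ddx3y at 0.535, 0.562, 0.479, 0.671, 142, 157, 151 and 156 CPM. Pgr stood at 28.8, 25.2, 25.4, 42.9, 0.0654, 0.146, 0.0318 and 0.0340 CPM. By class, Pgr was highest in epithelial-like cells, at 350 CPM. Next were mast-like cells, at 4.92 CPM, and fibroblast-like cells, the largest class, at 4.75 CPM. The Pgr level over all cells of a suffix therefore depends on the epithelial-like cells there, but not on them alone. Over all cells, suffixes 5 to 8 held only 2, 4, 1 and 1 Pgr UMIs. Fibroblast-like cells made up 43.9%, 36.7%, 33.4% and 31.8% of cells there, so few of their Pgr UMIs came from these suffixes. The cause was not tested. Epithelial-like cells made up 3.13%, 2.63%, 3.76%, 4.09%, 0%, 0%, 0% and 0% of cells. Over all cells, Trpv4 stood at 9.30, 12.3, 13.2, 12.1, 14.9, 18.7, 19.0 and 18.6 CPM, and macrophage-like cells made up 14.9%, 15.7%, 20.7%, 20.4%, 27.0%, 22.1%, 26.9% and 26.7% of cells. The share of lymphatic endothelial-like cells ranged from 1.53% to 4.20% with a median of 3.17%.

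Of 8 fibroblast-like clusters, 3 drew 90% or more of their cells from one set of 4 suffixes: suffixes 1 to 4 gave 0.661% of cluster 3, 1.44% of cluster 13, 90.4% of cluster 8 and, just short of that, 89.1% of cluster 6, beside 45.0% of all cells. A capture-well effect shared by all cells could give such clusters, and would then split other classes as well. Of the 33 other clusters, 2 (6.06%, 0.743% to 20.2%), both epithelial-like, drew 90% or more from one set, and the upper limit passes the bound of 20% set for the test. Others leaned less far, with 83.6% of unnamed cluster 26 and 78.0% of macrophage-like cluster 0 from suffixes 5 to 8. A shared effect therefore stays open, as does an effect of the well on fibroblasts alone. The sex of the mice, which the design names, was not tested and also stays open. Cells were pooled within each sex before capture, so if the sets are the 2 wells, effects of well and sex cannot be told apart.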
